A study of Mus musculus with 8 samples.

How the data were processed

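Gene expression was measured on 8 mouse Illumina BeadChip arrays, 4 of CCL17-positive dendritic cells from lymph nodes (LN) and 4 of CCL17-negative dendritic cells from spleen. Group and replicate number were taken from the titles and source names of the samples. Per the labels' protocols, total RNA was isolated with TRIzol and biotinylated cRNA was hybridised. The arrays lay on 2 BeadChips. The first held replicates 1 and 2 of both groups and the second held replicates 3 and 4 of both groups.

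The deposited table of non-normalized values holds, per the file headers, a bead intensity for each probe and array on a linear scale. The deposited table also gives, per the file headers, a detection p-value for each probe and array. Its steps imply 936 negative control beads. The authors' processed values are on a log2 scale, with the same quantiles in every array and a median of 6.28 in each, and they had a correlation of at least 0.998989 with the log2 intensity of the same array, so the scale and direction were settled from the values. Partek is named in the submitters' processing notes, without a version or a role, and the scanner software, background step and order of steps are not given in the sources used here.

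Mean intensity per array ran from 239 to 521, median intensity from 65.0 to 88.2, and 30.4% to 33.1% of the 45281 probes had a detection p under 0.01. The number of arrays limits the precision. No pair of arrays was a repeat deposit: the highest correlation between 2 arrays was 0.992 and at most 0.00221% of intensities were equal. One blank line of the table was left out. A gene table paired 34903 of the probes with symbols: 34885 had 1 symbol, 18 had several and 10378 were not listed and stay unnamed here. By Entrez identifier, 34807 of the probes with 1 symbol matched the current mouse gene table, and 0 symbols changed. No genome was given, so no coordinates were used. Hbb-bs and Hbb-bt, like Hba-a1 and its copy, are nearly identical genes, so their separate levels are uncertain.

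Intensities were background-corrected with the negative controls inferred from the detection p, quantile-normalized and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Labels and tables were read with jsonlite 2.0.0, and the plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Probes were kept where the detection p was under 0.01 on at least 4 of the 8 arrays, without regard to group: 14726 probes passed, 12589 of them with 1 symbol and 2137 without. The brightest probe stood for each gene, which left 8248 of 19057 named genes. Of these, 3042 had more than 1 passing probe and 0 had probes called in opposite directions. A linear model with 2 group means was fitted with lmFit and eBayes with an intensity trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Values after a gene are the log2 fold of LN over spleen ± its standard error (SE), with n = 4 arrays per group, and every adjusted p of a gene comes from this limma test, which is two-sided.

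Where a gene was detected on all 4 arrays of one group and on 0 of the other, its level in the second group is only known to lie below the detection limit. Such genes are given as "at least N-fold", the mean of the bright group against the higher of the lowest detected signal and the dim probe's own signal on each array, with the adjusted p of the model. Where a gene was detected on only 1 array of a group, most of its values there lie near background, so the size of its fold is uncertain and only its direction and call are meant.

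In all 35 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. For each list the number of called members was counted over all genes tested and adjusted over the list alone. The lists covered maturation and migration, costimulation, chemokines, attractant receptors, secreted cytokines, MHC class I and II, type I interferon and interferon gamma responses, GM-CSF and STAT5, IL-4 and STAT6, TLR and NF-kappaB signalling, retinoic acid and TGF-beta regulation, the splenic CD11b subset, cDC1, lineage transcription factors, endocytic receptors, lysosome, actin and adhesion, glycolysis, cholesterol, cell cycle, apoptosis, and immediate early genes. Marker lists for T, B, NK, erythroid, macrophage, monocyte, neutrophil, plasmacytoid, platelet, stromal and Langerhans or epithelial-tract dendritic cells served to measure other cell types. Together they held 558 tested genes.

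The main design, the lists, the naming rule and the alternatives without a mention to the contrary were fixed before the data were examined. The rule named Ccl17 and the sort markers, the 10 largest called folds per direction among genes detected on every array with groups that did not overlap, the 5 largest bounds per direction, and up to 3 called members per list and direction, or the 3 largest folds where fewer than 3 were called. Among the largest folds and bounds, predicted genes (such as LOC, Gm or Rik names) were passed over for the next gene. Further called members of lists with 5 or fewer calls in a direction, the uncalled maturation genes Ccr7, Cd40, Cd83 and Relb, Siglech, and the single genes that the closing section adds were named after their values were seen.

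The fit was tested on simulated data for the comparison of LN and spleen over 8248 genes. Of 50 genes changed at each size, 4% were recovered at a log2 fold of 0.5, 42% at 1, 82% at 2 and 98% at 3, and 5 unchanged genes were called, 4.24% of all calls. A shifted list was called, with 0 calls among the lists that share no gene with it. The simulated genes varied independently of each other, so this does not test how correlation between genes affects the list calls. A smaller share of genes was changed than the 15.5% called in the data. The adjusted threshold depends on that share, so recovery in the data can differ from these values.

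Per the series text, spleen and LN cells of a sort came from the same mice and were sorted side by side, and the groups share replicate numbers. The deviations of same-numbered arrays from their group means had correlations of 0.31, 0.57, 0.27 and 0.54 over genes, all above 0.1. Same-BeadChip arrays with different numbers had correlations of 0.58, 0.41, 0.42 and -0.18. Same-numbered arrays always share a BeadChip, so these values cannot tell pairs from a BeadChip effect. That the numbers pair the samples is an assumption here. Replicate number as a block was therefore an alternative that is given wherever it changes a call or a count by more than 1.5 times.

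Alternatives covered background correction, offset, normalization, the authors' values, the detection filter, the choice of probe, the BeadChip as a block and alone, array weights, moderation, thresholds, set tests and leaving out each array in turn. Lists within single BeadChips and the block without the fourth pair were added after seeing the data.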

Results

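Dendritic cells were profiled from CCL17E/+ mice on a C57BL/6 background, a reporter strain in which EGFP marks cells that express the chemokine gene Ccl17. Spleens and lymph nodes, the latter mesenteric and peripheral, were taken 15 h after 100 µg of LPS, the bacterial endotoxin. From both organs cells without NK1.1 and CD8alpha but with CD11c and CD11b were sorted. EGFP-positive cells were kept from LN and EGFP-negative cells from spleen, with 4 arrays per group. The comparison asks how CCL17-expressing LN dendritic cells differ from splenic dendritic cells without CCL17 after the same stimulus. Organ and CCL17 status differ together between the groups, so no value here separates them. The samples came in parallel from the same mice per the series text, but the number of mice per sort and any pooling are not given in the sources used here, and p-values measure the spread between these samples.

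Mean intensity per array was 521, 482, 417 and 334 for LN replicates 1 to 4 and 510, 483, 345 and 239 for spleen replicates 1 to 4. Between 13743 and 14985 probes were detected per array. LN arrays had a mean correlation of 0.985 to 0.987 with the other arrays of their group. Spleen replicates 1 to 3 reached 0.973 to 0.977, and spleen replicate 4 reached 0.951. On the first principal component, with 49.4% of the variance, the LN arrays lay between 28.1 and 35.3 and the spleen arrays between -63.3 and -16.6.

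**Figure D1:**
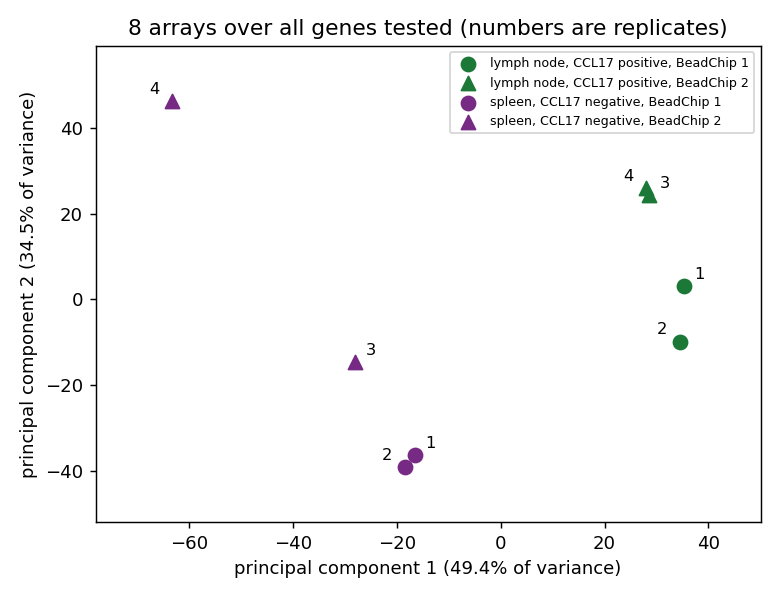
Each point is 1 of the 8 arrays on the first 2 principal components (49.4% and 34.5% of the variance) of normalized log2 intensity, with colour for group, marker for BeadChip and the number for replicate. LN arrays sit at 28.1 to 35.3 on the horizontal axis and spleen arrays at -63.3 to -16.6, with spleen replicate 4 at the far end.

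Ccl17, the ligand of CCR4 whose reporter defined the sort, had a mean log2 intensity of 12.51 ± 0.33 (SD, n = 4) in LN cells and 6.24 ± 0.50 (SD, n = 4) in splenic cells. It was 77.2-fold higher in LN (log2 fold 6.27 ± 0.28, adjusted p 1.13e-06), and an exact permutation test gave p = 0.0286, the smallest that 70 arrangements allow. This checks the labels and is no finding, since the cells were sorted on it. Itgax, which encodes CD11c, was detected on 3 arrays of each group and had a log2 fold of -0.51 ± 0.37 (adjusted p 0.436). Itgam, which encodes CD11b, was detected on 1 LN array and on 0 spleen arrays, and Cd8a and Klrb1c, which encode CD8alpha and NK1.1, on 0 of the 8 arrays. These 3 genes were not tested.

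Single genes detected on every array had large folds in both directions. Aqp9, a channel for water and glycerol, was 25.2-fold higher in LN (4.65 ± 0.33, adjusted p 1.59e-05). Ttc39a was 22.4-fold higher (4.48 ± 0.33, adjusted p 1.95e-05), and Aldh1a2, the dehydrogenase that makes retinoic acid, was 14.2-fold higher (3.83 ± 0.44, adjusted p 0.000264). Fndc5, the precursor of irisin (3.51 ± 0.24, adjusted p 1.42e-05), Car2, a carbonic anhydrase (3.29 ± 0.20, adjusted p 9.38e-06), and Lyz2, the myeloid lysozyme (3.25 ± 0.48, adjusted p 0.00123), were higher too. So were Apol7c, of the apolipoprotein L family (3.22 ± 0.31, adjusted p 9.58e-05), and Sult1a1, a phenol sulfotransferase (3.21 ± 0.30, adjusted p 7.8e-05). Fam110a (3.10 ± 0.19, adjusted p 1.02e-05) completed the 10 largest with Ccl17, with predicted genes passed over. In the other direction Cxcl10, the interferon-induced ligand of CXCR3, was 18.5-fold higher in spleen (-4.21 ± 0.25, adjusted p 9.38e-06). Cyp4f16, a cytochrome P450, was 14.2-fold higher in spleen (-3.83 ± 0.52, adjusted p 0.000743) and the chemokine Ccl4 11.7-fold (-3.55 ± 0.50, adjusted p 0.00087). Adam11 (-3.25 ± 0.35, adjusted p 0.000197), the uridine phosphorylase Upp1 (-3.15 ± 0.26, adjusted p 3.45e-05), the cytoskeletal adaptor Pstpip1 (-3.14 ± 0.29, adjusted p 7.8e-05) and the semaphorin Sema4f (-3.13 ± 0.35, adjusted p 0.000232) were also lower in LN. So were Isg20, an interferon-induced exonuclease (-3.03 ± 0.20, adjusted p 1.35e-05), Alox5ap, which is needed for leukotriene synthesis (-2.99 ± 0.43, adjusted p 0.000996), and Lag3, an inhibitory receptor for MHC class II (-2.95 ± 0.37, adjusted p 0.000446).

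In all, 1282 of 8248 genes (15.5%) were called, 658 higher and 624 lower in LN, and 886 of them had a log2 fold of at least 1 in size. In 1213 of the calls the 4 LN values all lay above or all below the 4 spleen values. Among all genes tested 22.2% had such separate groups, against 2.86% by chance. Scaling each array by its median in place of its quantiles moved the median log2 fold of all genes from 0.03 to 0.24, and 623 genes were then higher and 313 lower, so that 66.6% of the calls were higher against 51.3% before. Without spleen replicate 4, 1986 genes were called, 1003 higher and 983 lower. Within the first BeadChip alone 1813 were called and within the second alone 358.

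**Figure D2:**
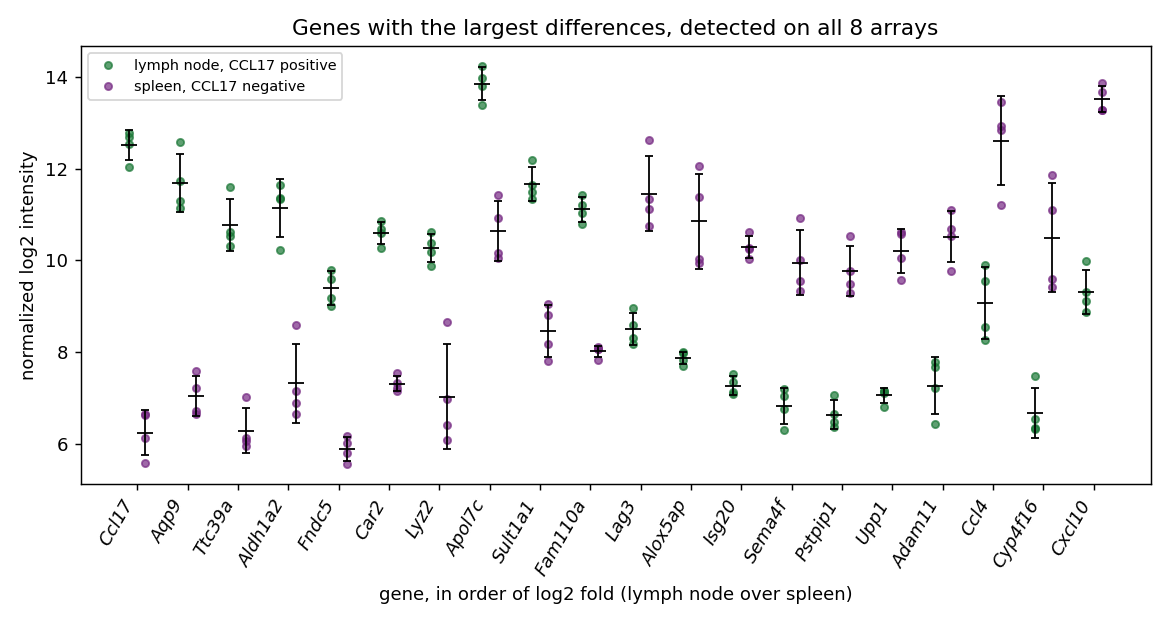
Points are normalized log2 intensities of single arrays for the genes with the largest called log2 folds in each direction, detected on all 8 arrays, with predicted genes passed over. Colour marks the group and bars the mean ± SD of 4 arrays. Ccl17 spans the widest gap, from a mean of 6.24 in spleen to 12.51 in LN.

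Some genes were detected on all 4 arrays of one group and on 0 arrays of the other, 91 of the called genes only in LN and 25 only in spleen. For these only a bound on the fold is known. Syngr3, a synaptic vesicle protein, was at least 22.8-fold higher in LN (adjusted p 3.41e-06), and Ppp1r1a, a protein phosphatase inhibitor, at least 22.8-fold (adjusted p 4.79e-07). The scaffold gene Slc9a3r2 was at least 17.4-fold higher (adjusted p 1.13e-06), Ccl22, the other ligand of CCR4, at least 13.3-fold (adjusted p 1.33e-05), and the semaphorin Sema6d at least 9.19-fold (adjusted p 0.000132). In spleen, Bex6 was at least 8.09-fold higher (adjusted p 0.000563), the succinate receptor Sucnr1 at least 4.76-fold (adjusted p 3.54e-05), and the kinase Dyrk3 at least 4.17-fold (adjusted p 0.00116). Ppargc1a, a coactivator of mitochondrial biogenesis, was at least 3.31-fold higher in spleen (adjusted p 4.84e-05) and Sh2d1b1, an adaptor of SLAM receptors, at least 2.88-fold (adjusted p 0.000317).

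Interferon-stimulated genes were lower in LN cells as a group. Of 32 measured genes of the type I interferon response, the antiviral programme, 26 were lower and 0 higher (28 lower adjusted over the list alone), and 0 of them had a positive fold. Besides Isg20 the largest were Oas2, a sensor of double-stranded RNA (-2.45 ± 0.23, adjusted p 8.36e-05), and the GTPase Mx2 (-2.30 ± 0.24, adjusted p 0.000137). Over the list the median was -1.32 (adjusted p = 1.33e-21, and adjusted p = 0.00739 with an estimated correlation), or -1.35 on the first BeadChip and -1.33 on the second. Of 30 interferon gamma response genes 10 were lower and 0 higher (14 and 1 adjusted over the list alone). These included Cxcl10, Cxcl9, another CXCR3 ligand (-2.92 ± 0.21, adjusted p 1.47e-05), and Il12rb2, a chain of the IL-12 receptor (-2.80 ± 0.26, adjusted p 7.8e-05, detected on 1 LN array and all spleen arrays, and -3.08 to -1.63 over the alternatives). That list had a median of -0.59 (adjusted p = 2.76e-08, and adjusted p = 0.0359 with an estimated correlation), or -0.55 on the first BeadChip and -0.51 on the second. Without spleen replicate 4, 16 of its genes were lower and 1 higher, and with replicate number as a block 14 and 1.

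Some markers of plasmacytoid dendritic cells, the main producers of type I interferon, were lower in LN too. The gate for CD11b should leave out most of these cells. Of 13 measured markers 5 were lower in LN and 0 higher (6 and 1 adjusted over the list alone): Lag3, the RNA sensor Tlr7 (-2.68 ± 0.37, adjusted p 0.000824), the interferon regulator Irf7 (-2.14 ± 0.33, adjusted p 0.00142), Pacsin1 (-1.40 ± 0.33, adjusted p 0.0153) and Bst2 (-0.79 ± 0.21, adjusted p 0.0318). Irf7 and Bst2 are also interferon-stimulated genes. Siglech, the surface lectin of these cells, had a log2 fold of -0.37 ± 0.32 (adjusted p 0.524). In all 8 of the 13 markers were not called, and 3 had a positive fold, the largest that of Spib (0.75 ± 0.26, adjusted p 0.0817). The list median was -0.41 (adjusted p = 0.00304, but adjusted p = 0.148 with an estimated correlation), or -0.43 on the first BeadChip and -0.62 on the second. Leaving out 1 array ended the calls of Pacsin1 without LN replicate 1 (adjusted p up to 0.0546) and Bst2 without LN replicates 1, 3 or 4 or spleen replicates 1 or 2 (adjusted p up to 0.0957), and 3 markers stayed lower without LN replicate 1.

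**Figure D3:**
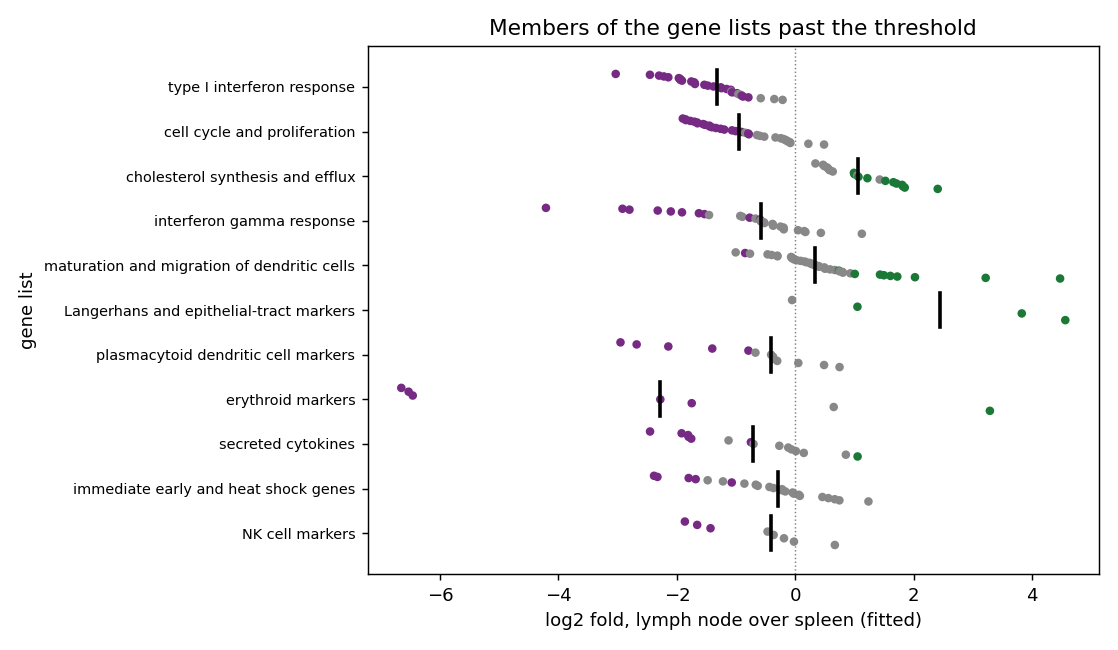
Each point is the fitted log2 fold (LN over spleen, horizontal axis) of 1 tested gene in the 11 called lists, green or purple where called higher or lower and grey otherwise, and each black line is a list median. The type I interferon response (-1.32) and cell cycle (-0.96) lists lie to the left of 0 and the cholesterol list (1.06) to the right.

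Cell cycle genes were lower in LN cells. Of 34 measured genes 20 were lower and 0 higher (22 lower adjusted over the list alone). Tk1, the thymidine kinase of DNA synthesis (-1.90 ± 0.29, adjusted p 0.00158), was detected on 1 LN array and on all spleen arrays. Cdca3, which triggers entry into mitosis (-1.85 ± 0.23, adjusted p 0.000459), and the chromatin protein Hmgb2 (-1.85 ± 0.27, adjusted p 0.00114) were lower too. The list median was -0.96 (adjusted p = 1.51e-10, and adjusted p = 0.00739 with an estimated correlation), or -0.99 on the first BeadChip and -0.87 on the second. Without LN replicate 1 or without spleen replicate 2, 13 of its genes were lower.

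Erythroid transcripts went in the same direction as the cell cycle and interferon genes. The globin genes Hba-a1 (-6.66 ± 0.69, adjusted p 0.000137), Hbb-bs (-6.53 ± 0.62, adjusted p 8.5e-05) and Hbb-bt (-6.46 ± 0.55, adjusted p 4.25e-05) were lower in LN, each detected on 3 LN arrays and all spleen arrays. Alas2, the first enzyme of erythroid haem synthesis, was at least 2.48-fold higher in spleen (adjusted p 0.00121), and Tfrc, the transferrin receptor, was lower in LN (-1.75 ± 0.34, adjusted p 0.00593). Car2, also made by erythrocytes, was higher in LN. In all 5 of 7 measured markers were lower and 1 higher (5 and 1 adjusted over the list alone), with a median of -2.28, or -1.75 with Alas2 at its bound (adjusted p = 0.00821, but adjusted p = 0.35 with an estimated correlation). The medians were -1.81 on the first BeadChip and -2.75 on the second. The call was lost without spleen replicate 4, with an adjusted p of 0.0628 and 2 higher members, and within the first BeadChip, with an adjusted p of 0.0751. Over all alternatives the adjusted p ran from 3.28e-05 to 0.379.

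Some natural killer cell markers were also lower in LN, although NK1.1-positive cells were gated out. Of 8 measured markers 3 were lower and 0 higher (3 and 1 adjusted over the list alone). Klra3, a Ly49 receptor, was at least 2.48-fold higher in spleen (adjusted p 0.000714). Il18rap, a chain of the IL-18 receptor (-1.66 ± 0.30, adjusted p 0.00357, detected on 2 LN arrays), and the protease Ctsw (-1.43 ± 0.24, adjusted p 0.00247) were lower in LN. As a list they had a median of -0.42 (adjusted p = 0.0205, but adjusted p = 0.133 with an estimated correlation), or -0.55 on the first BeadChip and -0.42 on the second. The call was lost without spleen replicate 4 (adjusted p 0.0566), within the first BeadChip (adjusted p 0.0663), with the block but without the fourth pair (adjusted p 0.0631) and where detection on all 8 arrays was required (adjusted p 0.317), within a range of 0.0131 to 0.317 over the alternatives. Leaving out spleen replicate 4 and the block each called 1 marker higher.

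Genes of cholesterol synthesis and export were higher in LN cells, and all 20 measured members had a positive fold. Of these 11 were called higher and 0 lower (15 higher adjusted over the list alone). Sqle, the squalene epoxidase (2.41 ± 0.36, adjusted p 0.00122), Stard4, a sterol carrier (1.85 ± 0.21, adjusted p 0.000252), and Mvd of the mevalonate pathway (1.82 ± 0.31, adjusted p 0.0029) led the list. Its median was 1.06 (adjusted p = 7.98e-09, but adjusted p = 0.0889 with an estimated correlation), or 0.96 on the first BeadChip and 1.25 on the second.

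Some genes of dendritic cell maturation and migration were higher in LN cells, while 31 were not called. Of 41 measured genes 9 were higher and 1 lower (15 and 1 adjusted over the list alone), led by Ccl22, Apol7c and Lad1, an anchoring protein (2.02 ± 0.32, adjusted p 0.00178). Traf1, an adaptor of TNF receptors, was lower (-0.85 ± 0.14, adjusted p 0.00223). Some uncalled members were picked out after their values were seen. Ccr7, the receptor that guides dendritic cells to lymph nodes, had a log2 fold of -0.03 ± 0.23 (adjusted p 0.961) and the costimulatory receptor Cd40 0.17 ± 0.31 (adjusted p 0.797). The maturation marker Cd83 had 0.18 ± 0.21 (adjusted p 0.656) and the NF-kappaB subunit Relb -0.05 ± 0.24 (adjusted p 0.923). The fold of Cd40 ran from -0.22 to 0.56 over the alternatives. Over all members the median was 0.34 (adjusted p = 0.00262, but adjusted p = 0.0897 with an estimated correlation), or 0.21 on the first BeadChip and 0.44 on the second. With the block 16 were higher and 2 lower, and without spleen replicate 4 14 and 2.

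Costimulation and checkpoint genes went both ways. Of 16 measured costimulation and checkpoint genes 3 were higher in LN and 5 lower (4 and 8 adjusted over the list alone). The nectin family members Nectin2 (1.98 ± 0.26, adjusted p 0.000539) and Pvr (1.55 ± 0.24, adjusted p 0.00156) and Pdcd1lg2, which encodes PD-L2 (1.66 ± 0.31, adjusted p 0.00444) were higher. The B7 family members Cd276 (-1.98 ± 0.24, adjusted p 0.000357) and Cd80 (-1.64 ± 0.27, adjusted p 0.00202), the CD27 ligand Cd70 (-1.74 ± 0.28, adjusted p 0.00202), the CD137 ligand Tnfsf9 (-1.56 ± 0.40, adjusted p 0.0236) and the inhibitory receptor Havcr2 (-0.95 ± 0.27, adjusted p 0.0405) were lower. The list median of -0.69 did not pass (adjusted p = 0.188, and adjusted p = 0.272 with an estimated correlation). Single arrays decided the calls of Tnfsf9 and Havcr2, lost for Tnfsf9 without LN replicates 2 or 3 (adjusted p up to 0.0691) and Havcr2 without LN replicates 1, 2 or 3 or spleen replicates 2 or 3 (adjusted p up to 0.114), which left 3 lower without LN replicate 2 or 3.

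Chemokine genes went both ways. Of 15 measured 8 were higher in LN and 4 lower (8 and 4 adjusted over the list alone). Beside Ccl22, Cx3cl1, the membrane-bound fractalkine, was at least 5.68-fold higher (adjusted p 1.97e-05) and Cxcl13, the attractant of B cells, at least 3.29-fold (adjusted p 0.000148). Lower in LN were Cxcl10, Cxcl9, Ccl4 and its relative Ccl3 (-2.49 ± 0.33, adjusted p 0.000599). The list median was 0.92, or 0.76 with genes at their bounds (adjusted p = 0.14, and adjusted p = 0.579 with an estimated correlation). It ran from -0.47 to 1.55 over the alternatives. Among 10 attractant receptors 1 was higher and 3 were lower (1 and 3 adjusted over the list alone; median -0.12, adjusted p = 0.427). The leukotriene receptor Cysltr1 was at least 4.09-fold higher (adjusted p 4.36e-05), while Cxcr5, the receptor of CXCL13 (-2.01 ± 0.26, adjusted p 0.00056), Ccrl2 (-1.62 ± 0.40, adjusted p 0.021) and Ccr6, the receptor of CCL20 (-1.16 ± 0.26, adjusted p 0.0118), were lower. The call was lost for Ccrl2 without LN replicates 3 or 4 or spleen replicates 1 or 2 (adjusted p up to 0.0598), and with the block 2 receptors were higher.

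Some secreted cytokines were lower in LN cells. Of 15 measured 6 were lower and 1 higher (8 and 2 adjusted over the list alone). Il27, a subunit of IL-27 (-2.45 ± 0.24, adjusted p 9.58e-05, detected on 3 LN arrays), the inflammatory cytokine Tnf (-1.92 ± 0.33, adjusted p 0.00292) and Il16 (-1.81 ± 0.41, adjusted p 0.0122) were lower, and Tnfsf13b, the B cell survival factor BAFF, was higher (1.05 ± 0.24, adjusted p 0.0125, detected on 3 spleen arrays). The list median was -0.71 (adjusted p = 0.0126, but adjusted p = 0.0998 with an estimated correlation), or -0.81 on the first BeadChip and -0.54 on the second. That call was also lost without the filter on dim probes, which brought undetected members in (median -0.06, adjusted p 0.0971, within a range of 0.00283 to 0.0998 over the alternatives). Some immediate early genes, which also respond to handling, were lower in LN as well. Of 24 measured 5 were lower, 0 higher and 19 not called (6 and 1 adjusted over the list alone). The lower ones were Ier3 (-2.39 ± 0.26, adjusted p 0.000207), the transcription factors Egr1 (-2.33 ± 0.37, adjusted p 0.00195), Egr2 (-1.80 ± 0.38, adjusted p 0.00855, detected on 3 LN arrays) and Jun (-1.68 ± 0.49, adjusted p 0.0422), and the phosphatase Dusp2 (-1.07 ± 0.15, adjusted p 0.000997). That list had a median of -0.30 (adjusted p = 0.0205, but adjusted p = 0.246 with an estimated correlation), or -0.20 on the first BeadChip and -0.37 on the second, with an adjusted p of 0.101 within the first and a range of 0.00241 to 0.246 over the alternatives. With the block 8 were lower and 1 higher, without spleen replicate 4 8 and 2, and the call was lost for Jun without LN replicates 1, 2, 3 or 4 or spleen replicate 3 (adjusted p up to 0.127).

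Single genes of retinoic acid metabolism and the few measured members of the epithelial-tract list were mostly higher in LN cells. Stra6, a retinol transporter, was at least 7.2-fold higher in LN (adjusted p 4.36e-05) beside Aldh1a2, the plasminogen activator Plat (1.52 ± 0.27, adjusted p 0.00318) and the retinoic acid receptor Rarb, at least 1.58-fold (adjusted p 0.0105). Lower were the TGF-beta mediator Smad3 (-0.98 ± 0.26, adjusted p 0.0268), the integrin Itgav (-0.91 ± 0.26, adjusted p 0.0392) and the receptor Rarg (-0.78 ± 0.23, adjusted p 0.0482). Of 18 measured genes of that list 4 were higher and 3 lower (6 and 3 adjusted over the list alone), and its median of 0.41 did not pass (adjusted p = 0.191, and adjusted p = 0.272 with an estimated correlation). None of the 3 lower calls held on leaving out each array, being lost for Smad3 without LN replicates 1 or 3 or spleen replicates 1 or 3 (adjusted p up to 0.0783), Itgav without LN replicates 1, 2 or 3 or spleen replicates 2 or 3 (adjusted p up to 0.121) and Rarg without LN replicates 1, 2, 3 or 4 or spleen replicates 1, 2 or 4 (adjusted p up to 0.137). Of 4 measured Langerhans and epithelial-tract markers 3 were higher and 0 lower (3 and 0 adjusted over the list alone): Itgae, which encodes CD103 (4.56 ± 0.35, adjusted p 2.22e-05, detected on 3 spleen arrays), Aldh1a2 and Mfge8, a bridge for apoptotic cells (1.05 ± 0.19, adjusted p 0.00388). Its median was 2.44 (adjusted p = 0.00301, but adjusted p = 0.0889 with an estimated correlation), or 2.47 on the first BeadChip and 2.41 on the second. That size rests on 4 detected members, since the others of the 19 with a named probe did not pass the detection filter. Itgae is also in the cross-presenting list and Aldh1a2 in the retinoic acid list, so these calls do not identify a cell type. The median was 0.03 without the filter on dim probes (adjusted p 0.0448, within a range of 0.000874 to 0.0889 over the alternatives).

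Markers of the splenic CD11b subset split within the list, with 5 of 17 higher in LN and 4 lower (5 and 6 adjusted over the list alone). The list median was -0.02 (adjusted p = 0.929) and ran from -0.58 to 0.55 over the alternatives. Higher were Lyz2, the lectin Mgl2, at least 3.68-fold (adjusted p 0.00026), the Fc receptor Fcgr3, at least 2.98-fold (adjusted p 0.000338), the adhesion molecule Esam (1.36 ± 0.19, adjusted p 0.000948) and the tetraspanin Cd9 (1.23 ± 0.21, adjusted p 0.00246). Lower were the transcription factor Tbx21 (-3.39 ± 0.34, adjusted p 0.000108, detected on 3 LN arrays), the Notch target Dtx1 (-2.93 ± 0.32, adjusted p 0.000207), the decoy receptor Il1r2 (-2.39 ± 0.20, adjusted p 3.89e-05) and Dscam, at least 2.21-fold higher in spleen (adjusted p 0.0153). The call was lost for Dscam without LN replicate 4 (adjusted p up to 0.0551). Of 12 measured genes of the CD8 and cross-presenting lineage 1, Itgae, was higher and 2 were lower (2 and 2 adjusted over the list alone; median -0.17 and mean 0.03 with the test pointing downward, adjusted p = 0.566): Septin3 (-1.94 ± 0.30, adjusted p 0.00171, detected on 3 LN arrays) and Ifi205 (-1.70 ± 0.19, adjusted p 0.000202), itself interferon-inducible. With the block or without spleen replicate 4, 2 were higher.

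Of 30 measured lineage and transcription factor genes 2 were higher in LN and 4 lower (2 and 4 adjusted over the list alone; median -0.18, adjusted p = 0.112). Klf2, a regulator of quiescence and trafficking (-1.83 ± 0.42, adjusted p 0.0137), Cebpb, a myeloid factor (-1.24 ± 0.18, adjusted p 0.00122), Mycl, a MYC relative of dendritic cells (-1.13 ± 0.22, adjusted p 0.00611), and the stem cell factor receptor Kit (-0.76 ± 0.19, adjusted p 0.0239) were lower. Runx1 (1.17 ± 0.33, adjusted p 0.0387, detected on 3 spleen arrays) and Etv3 (0.64 ± 0.18, adjusted p 0.0387) were higher. Leaving out 1 array ended the calls of Kit without LN replicates 1 or 2 or spleen replicates 1 or 3 (adjusted p up to 0.0725), Runx1 without LN replicates 1, 2 or 3 or spleen replicate 2 (adjusted p up to 0.106) and Etv3 without LN replicates 1, 2, 3 or 4 or spleen replicates 2 or 3 (adjusted p up to 0.118). With the block 2 were higher and 8 lower, the same numbers as without spleen replicate 4.

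Cytokine receptor pathways had called members in both directions. In the GM-CSF and STAT5 list 1 of 21 was higher and 4 were lower (3 and 5 adjusted over the list alone). Il2ra, a chain of the IL-2 receptor, was higher (0.91 ± 0.25, adjusted p 0.0328). The cytokine Osm (-1.76 ± 0.29, adjusted p 0.00243), the feedback inhibitors Socs3 (-1.49 ± 0.22, adjusted p 0.00122) and Cish (-0.78 ± 0.22, adjusted p 0.0399) and the kinase Pim1 (-1.36 ± 0.40, adjusted p 0.0439) were lower. The median of that list was 0.26, its mean -0.02 and its test pointed upward (adjusted p = 0.985). Among these, calls were lost for Il2ra without LN replicates 1, 2, 3 or 4 or spleen replicates 2 or 3 (adjusted p up to 0.0934), Cish without LN replicates 1, 2, 3 or 4 or spleen replicates 1 or 2 (adjusted p up to 0.111) and Pim1 without LN replicates 2, 3 or 4 or spleen replicates 1 or 2 (adjusted p up to 0.128), and with the block or without spleen replicate 4 3 were higher. In the IL-4 and STAT6 list 3 of 16 were higher, Ccl22, Mgl2 and Pdcd1lg2, and 3 lower, the transglutaminase Tgm2 (-2.86 ± 0.20, adjusted p 1.42e-05), Egr2 and Cish (4 and 5 adjusted over the list alone). Its median was -0.12 and its mean 0.14, with the test pointing downward (adjusted p = 0.839), and without spleen replicate 4 5 were lower.

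Receptors of microbial products and antigen presentation genes differed at single members. Of 35 measured TLR and NF-kappaB genes 6 were lower in LN and 0 higher (7 and 2 adjusted over the list alone; median -0.16, adjusted p = 0.128). Tlr7, Tlr5, the flagellin receptor (-1.29 ± 0.39, adjusted p 0.0475, detected on 1 LN array), and the adaptor Ticam2 (-1.21 ± 0.21, adjusted p 0.003) were the largest. With the block 8 were lower and 4 higher, and without LN replicate 4 2 were lower. Without LN replicate 1 or spleen replicate 3 it was 3, and without spleen replicate 4 2 were higher. Of 19 MHC class II genes 2 were lower and 0 higher (2 and 0 adjusted over the list alone; median -0.06, adjusted p = 0.839). They were the ubiquitin ligase Marchf1, which removes MHC class II from the surface (-1.56 ± 0.41, adjusted p 0.027), and H2-Oa, a brake on peptide loading (-1.20 ± 0.26, adjusted p 0.00973), whose partner H2-Ob had -1.16 ± 0.38 (adjusted p 0.0654, or 0.0272 with the block, 0.0188 without spleen replicate 1 and 0.0419 without spleen replicate 4). Of 22 MHC class I genes 2 were higher, the lipid-presenting Cd1d1 (1.72 ± 0.22, adjusted p 0.000489) and Sec61b (0.81 ± 0.22, adjusted p 0.0286), and 3 lower, the class I transactivator Nlrc5 (-0.87 ± 0.26, adjusted p 0.0485), H2-M3 (-0.63 ± 0.16, adjusted p 0.0199) and the immunoproteasome subunit Psmb10 (-0.52 ± 0.14, adjusted p 0.0328), with 2 and 3 adjusted over the list alone, a median of -0.12 and a mean of 0.01, with the test pointing downward (adjusted p = 0.693). Calls were lost for Tlr5 without LN replicates 1, 2, 3 or 4 or spleen replicate 3 (adjusted p up to 0.122), Marchf1 without LN replicates 1 or 4 or spleen replicate 3 (adjusted p up to 0.0888), Sec61b without LN replicates 1, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.0903), Nlrc5 without LN replicates 1, 2, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.133), H2-M3 without LN replicates 1 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.0694) and Psmb10 without LN replicates 1, 2 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.104). With the block or without spleen replicate 4, 2 MHC class II genes were higher.

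Markers of lymphocytes and other cell types were measured beside these groups. Of 7 T cell markers Thy1 was higher in LN (2.67 ± 0.30, adjusted p 0.000229, detected on 1 spleen array) and the costimulator Icos lower (-1.43 ± 0.24, adjusted p 0.00221), while Il7r had 0.72 ± 0.47 (adjusted p 0.383); the list had a median of 0.35 (adjusted p = 0.936) and the same counts, 1 and 1, adjusted over the list alone. Of 9 B cell markers 1, the inhibitory receptor Cd22 (-2.13 ± 0.40, adjusted p 0.00471, detected on 1 LN array), was lower and 0 were higher (1 and 0 adjusted over the list alone; median -0.37, adjusted p = 0.237). Leaving out 1 array moved that median to between -0.56 (without LN replicate 3) and -0.12 (without LN replicate 1). The kinase Blk had -1.26 ± 0.46 (adjusted p 0.0953, or 0.0275 with the block and 0.0321 with the BeadChip as a block). Spib had 0.75 ± 0.26 (adjusted p 0.0817, or 0.049 with the BeadChip as a block). With replicate number as a block 2 were lower. Of 15 macrophage markers Apoe, a lipid carrier (1.52 ± 0.28, adjusted p 0.00401, detected on 3 spleen arrays), was higher and Spic, the factor of red pulp macrophages (-2.73 ± 0.19, adjusted p 1.42e-05), lower, with the complement gene C1qc at 1.04 ± 0.33 (adjusted p 0.0629, or 0.0285 with the block and 0.00459 without spleen replicate 4). That list had a median of 0.60 (adjusted p = 0.442; 1 and 1 adjusted over the list alone), or 0.29 without spleen replicate 1. It was called within the first BeadChip (adjusted p 0.0343, within a range of 0.0343 to 0.985 over the alternatives), and with the block or without spleen replicate 4 5 were higher.

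Of 15 monocyte markers 2 were higher in LN, the lysozymes Lyz2 and Lyz1 (2.94 ± 0.47, adjusted p 0.00201), and 5 lower (2 and 6 adjusted over the list alone; median -0.14, adjusted p = 0.249). The lower ones were Ifitm6 (-2.56 ± 0.39, adjusted p 0.00148), the Fc receptor Fcgr4 (-2.17 ± 0.28, adjusted p 0.000491), Gpr141 (-1.82 ± 0.28, adjusted p 0.00158), the calcium binder S100a4 (-1.11 ± 0.28, adjusted p 0.0239) and Plac8 (-0.85 ± 0.16, adjusted p 0.00475). One call was lost, that of S100a4 without LN replicates 1, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.075). Of 3 neutrophil markers 0 were higher and 0 lower over all genes tested in limma, 1 at an unadjusted p under 0.05, and 0 adjusted over the list alone (median -0.28, adjusted p = 0.936). They were Stfa2 at 0.67 ± 0.28 (adjusted p 0.156), Lcn2 at -0.46 ± 0.34 (adjusted p 0.448) and Prg2 at -0.28 ± 0.30 (adjusted p 0.64). The 1 measured platelet marker, the tubulin Tubb1, was at least 1.57-fold higher in LN (adjusted p 0.00542; 1 higher adjusted over the list alone, list median 1.30, or 0.65 at its bound, adjusted p = 0.14). Of 3 stromal markers 1, Cxcl13, was higher (1 adjusted over the list alone; median 0.08, adjusted p = 0.291), and Eng had 0.08 ± 0.29 (adjusted p 0.901) and Pecam1 -0.14 ± 0.38 (adjusted p 0.871).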

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

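All tests of explanations in this part, those of probe pairs, BeadChips, globin and plasmacytoid markers, were chosen only after the result was seen. Their 95% intervals come from resampling genes, probes or markers, so they hold no spread between arrays or mice.

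Within each group of 4 arrays, a value was set apart where its gap to the nearest other value passed the critical share of the whole range in Dixon's test, which chance gives in about 1 of 20 groups. Of 454 groups of values 26 (5.73%) were set apart, 17 in spleen and 9 in LN, and 15 of them were spleen replicate 4. Values below are log2 intensities, with the gap as a share of the range in parentheses.

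In spleen replicate 4, Tlr7 read 8.82 against 9.91 to 10.01 (0.918), Itgae 5.47 against 6.96 to 7.13 (0.894) and Tpp1 5.50 against 7.29 to 7.60 (0.849) in the other spleen arrays. Also low in that array were Cd40 at 11.93 against 13.18 to 13.35 (0.878), Kif1a at 8.26 against 10.15 to 10.49 (0.847) and H2-M3 at 11.50 against 11.60 to 11.61 (0.907). High in that array were Irf7 at 14.66 against 12.99 to 13.25 (0.842), Nlrc5 at 13.65 against 12.51 to 12.61 (0.913), Icos at 8.49 against 8.07 to 8.11 (0.906) and Jun at 11.10 against 8.75 to 9.11 (0.847). Tnfsf9 at 9.09 against 7.28 to 7.52 (0.868) and Kif11 at 7.38 against 6.40 to 6.56 (0.843) were high there too. The mean of the type I interferon list was 11.09 against 11.28 to 11.28 (0.981) in that array, and that of the lineage and transcription factor list 10.65 against 10.44 to 10.47 (0.869). Its mean correlation with its group was 0.951 against 0.973 to 0.977 (0.85). In spleen replicate 3, Stra6 read 4.35 against 4.49 to 4.51 (0.875) and the mean of the cytokine list 9.02 against 8.82 to 8.84 (0.88).

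Among LN arrays, replicate 3 gave Kif2c 6.58 against 6.11 to 6.13 (0.952), Upp1 6.81 against 7.11 to 7.15 (0.888), Il2ra 9.20 against 9.50 to 9.54 (0.876) and a cytokine list mean of 8.28 against 8.12 to 8.13 (0.94). Replicate 2 gave Ctsz 12.32 against 12.59 to 12.63 (0.882), Kit 11.52 against 12.05 to 12.13 (0.863) and Sucnr1 4.61 against 4.97 to 5.04 (0.832). Replicate 1 gave Cd276 6.58 against 5.94 to 6.04 (0.841) and replicate 4 gave Ticam2 7.66 against 8.33 to 8.39 (0.911).

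Spleen replicate 4 stood apart from the other spleen arrays, and without it 1986 genes were called in place of 1282. The correlation between probes of a gene cannot decide on another mix or state of cells as the whole cause. Over 2189 genes with a pair of probes it was 0.234 (95% interval 0.188 to 0.277) for the deviation of spleen replicate 4. It was 0.852 for the difference between LN and spleen, which averages over more arrays, a ratio of 0.275 (0.224 to 0.326). Other differences within a group were low too, with 0.449 for spleen replicate 1 against 2 and 0.379 for spleen replicate 3 against 1 and 2. LN replicates 3 and 4 against 1 and 2 gave 0.244. A difference between the BeadChips as the whole cause is argued against, but only by a comparison of single arrays. Over 9781 probes spleen replicate 3, on the same BeadChip, shifted along the LN difference between BeadChips only 0.365 times as far. The interval of 0.353 to 0.377 resamples probes and says nothing on the spread between arrays. Measurement error of single probes goes with the low correlation between probes. Spleen replicate 4 was also the dimmest array, with a mean intensity of 239 against 334 to 521. It had the fewest detected probes, 13743 against 13903 to 14985. Whether its low signal has a part in its deviation was not tested and stays open. A BeadChip part, another mix or state of cells and other biology, such as differences between mice, stay open too.

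Cell cycle genes were lower in LN and higher in spleen. Erythroid RNA carried over in proportion to globin RNA is argued against as the whole cause. Between the spleen arrays with the most and the least globin RNA globin differed 8.18-fold. The excess of the 20 called cell cycle genes over LN had a ratio of only 0.901 (0.774 to 1.15, from resampling the genes). Over spleen replicates 1 to 4 the mean log2 intensity of the globin genes was 10.64, 12.5, 13.67 and 13.3. That of the called cell cycle genes was 8.23, 8.44, 8.25 and 8.35. RNA of dividing erythroid precursors need not follow globin, and the arrays with the most and the least globin lie on different BeadChips, so such precursors stay open. Each BeadChip held as many LN as spleen arrays, so a shift shared by all its arrays cannot part the groups. The design settles this without a test. The weaker list median of the BeadChips was -0.87, with -0.99 on the other. Organ and CCL17 status also remain open and cannot be separated by this design. A difference in proliferation between the populations is therefore a hypothesis here.

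Type I interferon genes were higher in spleen. Both BeadChips held equal numbers of LN and spleen arrays, so a shift shared by all arrays of a BeadChip cannot part the groups. The design settles this, and the medians are no test of it. The list median was -1.33 on the BeadChip with the weaker shift and -1.35 on the other. RNA of plasmacytoid dendritic cells carried over cannot be told apart from a response of the sorted cells, although the gate for CD11b should leave out most of those cells: the 11 markers of those cells outside the interferon list had a median of -0.37 with a 95% interval of -1.40 to 0.05, which includes the interferon median of -1.32. Organ and CCL17 status stay open and untested.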

How the results depend on the processing

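Lists within single BeadChips and the block without the fourth pair were the only tests in this part chosen after the result was seen. All 1282 called genes kept their direction in every alternative that tested them (970 of 970 where detection on all 8 arrays was required). With all 8 arrays, a block, another moderation or another threshold leaves the folds unchanged by design, so direction could not turn there. Of the calls, 1276 were also made with replicate number as a block, 1269 with the authors' values and 827 with median scaling. Ccl17 kept its call throughout, with log2 folds of 5.32 to 6.47 and an adjusted p of at most 0.000649. Of the values of named genes, 190 lost and 3 gained a call on leaving out 1 array against 1311 on the same side, and under the other alternatives 162 lost and 12 gained one against 2780. For lists these were 2 lost against 278, and 14 lost, 9 gained and 1 turned against 395. Besides the lysosome and macrophage lists, the chemokine (adjusted p 0.029), retinoic acid, monocyte and stromal lists (each 0.0411) gained a call without the filter on dim probes and the lineage list within the second BeadChip (adjusted p 0.0414). Medians of lists that did not pass moved by more than 1.5 times for many lists on leaving out 1 array, and their size is uncertain.

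The count of 1282 became 1740 with replicate number as a block (925 higher and 815 lower), and beyond the values given beside the results in the other parts the block changed no other call or moved a count by more than 1.5 times. Without the fourth pair the block gave 2616 (1312 and 1304, 31.7%). Array weights gave 2696 (1369 and 1327, 32.7%), the second BeadChip alone 358 (177 and 181, 4.34%, 358 with a log2 fold of at least 1), an adjusted p under 0.01 716 (360 and 356, 8.68%) and a test against a log2 fold of 1 173 (98 and 75, 2.10%). The 886 genes with a log2 fold of at least 1 became 545 without background correction, 584 with the authors' values and 1353 with every probe on its own. Median scaling left 313 lower genes, and without the detection filter 5.66% of genes were called. An estimated correlation left 3 of the 11 lists called, and fry called 20. Leaving out single arrays gave 887 to 1986 genes, 454 to 1003 higher, 418 to 983 lower, 10.8% to 24.1% of genes, 754 to 1002 with a log2 fold of at least 1, 9 to 11 lists, and 6.05 to 6.43 for Ccl17. The cause was not tested, except that a stricter threshold lowers the counts by construction. The erythroid list turned to a median of 0.65 (adjusted p 0.379) where detection on all 8 arrays was required, since the globins fail that filter. For dim genes, signal over background limits the fold to a bound.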

Other observations

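All tests of this part except the splits of the arrays were chosen only after the result was seen, apart from the gene lists, which were planned.

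Uptake and degradation genes differed at single members. Of 18 measured endocytic, Fc and complement receptors 4 were higher in LN and 2 lower (4 and 2 adjusted over the list alone; median 0.31, adjusted p = 0.472). Higher were Mgl2, Fcgr3, the scavenger receptor Stab1 (1.81 ± 0.29, adjusted p 0.00197, detected on 3 spleen arrays) and the lectin Clec4n (1.36 ± 0.38, adjusted p 0.0384). Lower were the activating Fc receptor Fcgr4 and its signalling chain Fcer1g (-1.45 ± 0.19, adjusted p 0.000627). Of 27 lysosomal genes 5 were higher and 2 lower (8 and 3 adjusted over the list alone; median 0.40, adjusted p = 0.112). That list was called without the filter on dim probes (adjusted p 0.0411), within the first BeadChip (adjusted p 0.0379) and with the block but without the fourth pair (adjusted p 0.0485), within a range of 0.0379 to 0.271 over the alternatives. Higher were the proteases Ctsa (2.04 ± 0.55, adjusted p 0.0301), Tpp1 (1.73 ± 0.46, adjusted p 0.0293, detected on 3 spleen arrays) and Ctsz (0.74 ± 0.20, adjusted p 0.0285), the glucuronidase Gusb (1.58 ± 0.27, adjusted p 0.00256) and the tetraspanin Cd63 (0.74 ± 0.16, adjusted p 0.0107). Lower were Cln3 (-1.91 ± 0.26, adjusted p 0.000632) and the cholesterol exporter of the lysosome Npc1 (-0.70 ± 0.21, adjusted p 0.0445). On leaving out 1 array calls were lost for Clec4n without LN replicates 1, 2, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.113), Ctsa without LN replicates 1, 3 or 4 or spleen replicates 1 or 2 (adjusted p up to 0.0961), Tpp1 without LN replicates 1, 2 or 4 or spleen replicate 3 (adjusted p up to 0.092), Ctsz without LN replicates 1, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.0854) and Npc1 without LN replicates 1, 2, 3 or 4 or spleen replicates 2 or 3 (adjusted p up to 0.134). With the block 10 lysosomal genes were higher and 5 lower, and without spleen replicate 4 9 and 5.

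Cytoskeleton, sugar metabolism and survival genes also went both ways. Of 40 actin and adhesion genes 6 were higher and 4 lower (6 and 4 adjusted over the list alone; median 0.00, adjusted p = 0.848). The GTPases Rhoc (2.85 ± 0.34, adjusted p 0.000312, detected on 2 spleen arrays) and Rhof (2.08 ± 0.35, adjusted p 0.00245) and the hyaluronan receptor Cd44 (1.73 ± 0.44, adjusted p 0.0241) were higher. The gut-homing integrin chain Itgb7 (-2.40 ± 0.43, adjusted p 0.00346), the myosin Myo1f (-1.78 ± 0.39, adjusted p 0.0102), Icam2 (-0.96 ± 0.27, adjusted p 0.0376, detected on 1 LN array) and the actin binder Tmsb10 (-0.87 ± 0.16, adjusted p 0.00493) were lower. Without LN replicate 3 or 4, 3 of that list were higher. Of 20 glycolysis genes 2 were higher, Pgk1 (0.95 ± 0.21, adjusted p 0.0102) and Tpi1 (0.84 ± 0.23, adjusted p 0.034), and 3 lower, the glucose transporter Slc2a3 (-2.15 ± 0.51, adjusted p 0.0156) and the regulators Pfkfb4 (-0.85 ± 0.16, adjusted p 0.00526) and Pfkl (-0.79 ± 0.21, adjusted p 0.0285), with 3 and 3 adjusted over the list alone and a median of -0.06 (adjusted p = 0.839). Of 27 apoptosis genes 3 were higher, the TNF receptor Tnfrsf1b (0.97 ± 0.22, adjusted p 0.0137), the adaptor Tradd, at least 1.42-fold (adjusted p 0.0181), and Bad (0.60 ± 0.17, adjusted p 0.0355). In that list 3 were lower, the BH3 proteins Bid (-0.94 ± 0.20, adjusted p 0.0107) and Bcl2l11 (-1.01 ± 0.27, adjusted p 0.028) and the caspase Casp6 (-1.14 ± 0.33, adjusted p 0.0422). It had 3 and 4 adjusted over the list alone, a median of 0.18 and a mean of -0.03, with the test pointing downward (adjusted p = 0.839). Not every call held on leaving out 1 array: it was lost for Cd44 without LN replicates 2, 3 or 4 or spleen replicate 2 (adjusted p up to 0.0719), Icam2 without LN replicates 1, 2 or 4 or spleen replicates 2 or 3 (adjusted p up to 0.117), Tpi1 without LN replicates 1, 2 or 4 or spleen replicates 2 or 3 (adjusted p up to 0.094), Slc2a3 without LN replicates 1 or 4 or spleen replicate 3 (adjusted p up to 0.0555), Pfkl without LN replicates 1, 2, 3 or 4 or spleen replicates 1 or 3 (adjusted p up to 0.0948), Tnfrsf1b without LN replicates 1 or 3 (adjusted p up to 0.0531), Tradd without LN replicate 1 (adjusted p up to 0.0598), Bad without LN replicates 1, 2, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.107), Bcl2l11 without LN replicates 1, 2 or 4 or spleen replicates 1 or 3 (adjusted p up to 0.0905) and Casp6 without LN replicates 1, 2, 3 or 4 or spleen replicates 1, 2 or 3 (adjusted p up to 0.126). With the block 5 glycolysis genes were higher and 5 apoptosis genes lower, and without spleen replicate 4 5 and 6, with 5 apoptosis genes higher.

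Single genes outside the lists were named after their values were seen. The carnitine and cation transporters Slc22a4 (3.93 ± 0.36, adjusted p 7.35e-05, detected on 2 spleen arrays), Slc22a5 (1.77 ± 0.26, adjusted p 0.00113) and Slc22a21 (2.14 ± 0.25, adjusted p 0.000328, detected on 3 spleen arrays) were higher in LN. In the leukotriene pathway Ltc4s, the synthase of leukotriene C, was at least 2.85-fold higher in LN (adjusted p 0.00017) beside Cysltr1, while Alox5ap was lower. Ahrr, the repressor of the aryl hydrocarbon receptor, was higher in LN (3.08 ± 0.21, adjusted p 1.42e-05, detected on 3 spleen arrays). Of 13 measured TNF receptors of the Tnfrsf root 5 were higher and 0 lower, and the group did not pass (adjusted p 0.272). Among the 5 were Tnfrsf11b, at least 1.89-fold higher (adjusted p 0.000539), Tnfrsf9 (1.61 ± 0.32, adjusted p 0.00632) and Tnfrsf4 (1.50 ± 0.18, adjusted p 0.000363).

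Among 248 groups of genes with a shared symbol root and at least 5 tested members, camera called 3, all interferon-inducible. Of 7 Oas genes 6 were lower in LN (adjusted p 0.000289), Oas3 among them (-2.22 ± 0.40, adjusted p 0.00356). Of 10 Ifi genes 6 were lower (adjusted p 0.0144). Of 5 Ifitm genes 3 were lower (adjusted p 0.0144), Ifitm1 (-0.87 ± 0.21, adjusted p 0.0197), Ifitm3 (-1.16 ± 0.18, adjusted p 0.00144) and Ifitm6. All 3 groups had an adjusted p = 0.97 with an estimated correlation. Kinesins, motors of the spindle and of transport, did not pass (adjusted p 0.0533). Of 21 measured 9 were lower, such as the mitotic Kif23 (-2.31 ± 0.19, adjusted p 3.78e-05), Kif2c (-1.65 ± 0.23, adjusted p 0.00084) and Kif11 (-1.56 ± 0.31, adjusted p 0.00643, detected on 1 LN array). In that family 2 were higher, the axonal motors Kif1a (1.54 ± 0.42, adjusted p 0.0339) and Kif1b (0.85 ± 0.20, adjusted p 0.0176). Single arrays ended the calls of Ifitm1 without LN replicate 3 or spleen replicate 3 (adjusted p up to 0.0649), Kif1a without LN replicates 1, 2, 3 or 4 or spleen replicate 3 (adjusted p up to 0.0924) and Kif1b without LN replicates 3 or 4 (adjusted p up to 0.0659).

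All 35 splits of the 8 arrays into groups of 4 were fitted. The real split called 1282 genes and the highest of the other splits called 0 in limma. Thus 1 of the 35 splits reached that count, a share under 0.05. The other splits hold LN and spleen arrays in each group, which widens their spread, so this share does not exclude chance. The same holds for the 886 genes with a log2 fold of at least 1, against 0 in the highest other split. The split by BeadChip called 0 genes at the adjusted threshold, 1758 at an unadjusted p under 0.05 against 2220 for the real split, and 1 list. For the number of lists chance cannot be excluded: the real split called 11 and 3 of the 35 splits, the real one included, called as many, so the highest other split also had 11. Of the 11 called lists 6 had their lowest p in the real split: type I interferon, interferon gamma, cell cycle, Langerhans and epithelial-tract, cytokine and NK lists. The other 5 had a lower p in at least 1 other split at the preset correlation, so this count cannot exclude chance for these. Splits that keep most LN arrays together still hold part of the real difference, so a low p there need not come from chance. With the real split counted, a p as low came in 2 of the 35 splits for the cholesterol, maturation and plasmacytoid lists. It came in 3 for the erythroid list and in 5 for the immediate early list. With an estimated correlation only the real split, 1 of 35, had a p as low for the cholesterol, maturation and plasmacytoid lists. At that setting the numbers were 8 for the erythroid list and 5 for the immediate early list. The 8 splits that part all 4 pairs are too few for a share under 0.05: there the real split called 1282 genes and 11 lists, and the highest other 0 genes and 9 lists.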
